A study of Mus musculus with 10 samples.

How the data were processed

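FAIRE-seq (formaldehyde-assisted isolation of regulatory elements) was carried out on mouse embryonic stem cells (ESC), epiblast stem cells (EpiSC), neural stem cells (NSC) and embryonic fibroblasts (MEF), and sheared purified genomic DNA was sequenced as a control. In this assay crosslinked chromatin is sheared and extracted with phenol and chloroform, and the DNA left in the aqueous phase, which is poor in nucleosomes, is sequenced. The labels give 10 samples in 5 groups of 2. For each of the 4 cell types 1 list of sites, filed with its replicate 2, was analysed here. The other 6 samples, the genomic control among them, were not analysed here as files. Whether each list comes from 1 replicate or from pooled reads is not given in the sources used here.

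Per the labels' protocols, libraries were amplified by PCR, fragments were selected on agarose gels and sequencing was done on an Illumina Genome Analyzer. Per the submitters' processing notes, CASAVA 1.8 was used and coordinates are on mouse build mm9. Each deposited list gives the chromosome, start and end of each site, a score of its own and a display value. The score was computed by the authors; how it was made, its unit, the aligner, the thresholds and the use of the control are not given in the sources used here. The names of the lists hold the word qeseq, the name of an enrichment caller. On testing, the display value in the deposited files differed by at most 1 from 100 times the score capped at 1000. Scores were used to describe, rank or filter sites within a list. Where scores of different lists are printed together, each belongs to its own list, and no difference is drawn between them, since a shared scale is not stated. Read depth is unknown, so a list may be longer because its library was deeper.

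Lists were read as 0-based half-open intervals and coordinates are printed 1-based. A site counted as overlapping another list where it shared at least 1 bp with a site of that list. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only, and neighbouring sites are not independent. The share that chance gives was taken from 100 circular shifts of the second list within each chromosome, by 1 Mb or more, and, as an alternative, from shifts of 50 to 500 kb, which keep the local density. Distances to the nearest site of another list were set beside 20 shifts of each kind, those of 50 to 500 kb being added after the data were seen. Sites of all 4 lists were merged into regions and put into 15 combinations. Sites were counted by midpoint in fixed windows of 100 kb, and Spearman correlations across the 23717 autosomal windows describe the lists; windows are not replicates. The relative density of a chromosome is its number of sites per Mb, up to the last site of any list, over the median of the 19 autosomes of the same list, and the density over the other lists is that value over the median of the other lists. With 1 list per cell type there is no spread between replicates and no test between cell types, and no p-value between them is given. If the lists were called against 1 shared control, part of any overlap may come from it.

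Sites were named by a rule set beforehand. For each cell type these are the 3 sites with the highest score in the list and the 3 with the highest score among sites in no other list. For ESC and EpiSC they are also the 3 windows of 100 kb with the most sites and none in the other list. Autosomal windows, the windows with the most sites of each list, the distal segment of chromosome 14, the runs of high-scoring sites and the sites 250 to 350 bp wide were chosen after the data were seen. The limits of that segment are those of the stretch of whole Mb with the greatest summed excess of NSC sites over their autosomal mean. A run is 5 or more neighbouring sites of a list at or above its 95th percentile of scores, with gaps of at most 5 kb. Wide sites are those of 2 kb or more.

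The settings varied, as chosen before the data were examined, were an overlap of at least 50% of the shorter site, the 50% of each list with the highest scores, lists of equal length (the 387312 highest-scoring sites of each), autosomes alone, shifts that keep the local density, merging of sites under 200 bp apart, and windows of 50 and 200 kb. Leaving out distal chromosome 14, chromosomes 7, 12 and 18, or chromosome 8 was added after the data were seen. The annotation of sites with genes and the tests of gene lists that were planned were not run, because no gene annotation of mm9 was used here; the gene table at hand is on another build, and no gene is named from coordinates.

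Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Overlap and merging were checked against bedtools 2.31.1, with identical counts. Simulated lists had sites placed uniformly at random on a single chromosome. With a planted overlap of 39.33% of 7821 sites, 39.3% was recovered. For 19023 sites of unrelated simulated lists the ratio of observed to shifted overlap was 1.03. The real lists are clustered and the simulated ones were not. The ratio that unrelated clustered lists would give was therefore not tested.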

Results

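Open chromatin was mapped by FAIRE-seq in 4 mouse cell types. ESC were E14 cells grown without serum in inhibitors of MEK and GSK3 with LIF, a condition known as the ground state of pluripotency. EpiSC were cells of the E3 line grown with FGF2 on fibroblast feeders, taken off the feeders before crosslinking, and stand for the primed state found after implantation. NSC were neural progenitors derived from ES cells and kept in FGF2 and EGF, and MEF were fibroblasts from midgestation embryos. Each group holds 2 samples, and 1 list of sites per cell type was analysed. 1 of the 3 labels that describe the MEF samples names NSC chromatin, whereas their title and cell type name fibroblasts, and the list is called MEF here on those grounds. The lists hold 1816946 sites together. The read depth behind them is unknown, and there is no replicate check of any difference between cell types.

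The number and size of open sites were compared first. NSC had the most sites, 555868, followed by ESC with 441855, MEF with 431911 and EpiSC with 387312. ESC sites were the widest, with a median of 373 bp (quartiles 245 and 607), against 338 bp in EpiSC, 333 bp in NSC and 323 bp in MEF. ESC sites thus covered 227 Mb, against 173 Mb for EpiSC, 249 Mb for NSC and 168 Mb for MEF. Sites were also packed more closely in ESC, where the median gap between neighbours was 1338 bp and 42.7% of gaps were under 1 kb. In EpiSC the median gap was 2343 bp with 29.2% under 1 kb, in NSC 1490 bp with 40.0%, and in MEF 2549 bp with 27.5%. The densest 10% of autosomal 100-kb windows held 30.3% of ESC sites, 25.5% of EpiSC sites, 25.4% of NSC sites and 22.6% of MEF sites. The median score given by the authors was 3.45 in ESC, 2.90 in EpiSC, 3.94 in NSC and 3.31 in MEF. These numbers move with depth and with the threshold of each list, neither of which is known.

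The cell types were then compared in pairs. ESC and EpiSC shared the most, with 45.0% of EpiSC sites (95% interval 44.8 to 45.1) overlapping an ESC site and 40.1% of ESC sites overlapping an EpiSC site. NSC and MEF followed, with 40.1% of MEF sites (40.0 to 40.3) in the NSC list. EpiSC stood closer to both somatic cell types than ESC did: 38.9% of EpiSC sites overlapped NSC and 29.1% MEF, against 33.1% and 24.4% of ESC sites. The EpiSC had been expanded on feeder fibroblasts before crosslinking. By shared bases the order was similar, with 23.6% of the bases of either list shared by ESC and EpiSC, 15.3% by NSC and MEF, 15.0% by EpiSC and NSC, 13.3% by ESC and NSC, 12.4% by EpiSC and MEF and 10.4% by ESC and MEF. Relative to lists shifted along the whole chromosome, the overlap of EpiSC sites with ESC was 2.77 times the mean of 16.2% (highest of the shifts 17.1%). The ratio was 2.32 for MEF sites in NSC, 2.11 for EpiSC sites in MEF as well as in NSC, 1.73 for ESC sites in NSC and 1.66 for MEF sites in ESC. Against shifts of 50 to 500 kb, which keep the local density, the lead of the pluripotent pair was gone. The ratio was then 1.86 for EpiSC sites in ESC, 1.94 for MEF sites in NSC and 1.83 for EpiSC sites in MEF. Every pair stayed above its shifted lists on both measures.

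The series sets ground-state against primed pluripotent cells. Of the ESC sites, 264872 (59.9%, 95% interval 59.8 to 60.1) had no overlap in EpiSC, and 213158 EpiSC sites (55.0%, 54.9 to 55.2) had none in ESC. The sites found in EpiSC and not in ESC were more often open in somatic cells: 32.4% overlapped NSC and 23.1% MEF, against 24.0% and 16.4% of the sites found in ESC and not in EpiSC. Accordingly 66.8% of the latter, and 55.7% of the former, lay in neither somatic list. At a fixed width of 250 to 350 bp the shares were 32.0% and 22.6% for EpiSC and 24.5% and 16.3% for ESC. These shares were not computed with lists of equal length. The EpiSC had been grown on feeder fibroblasts, and whether this bears on their shares in MEF was not tested. Sites common to both pluripotent cell types were wider (median 461 bp in the ESC list and 444 bp in the EpiSC list, against 332 and 286 bp) and more widely shared, 46.9% of those of the ESC list overlapping NSC and 36.4% MEF. With lists of equal length the numbers were close, with 221920 ESC sites (57.3%) without EpiSC overlap and 222999 EpiSC sites (57.6%) without ESC overlap. In the full lists similar numbers of sites overlapped, 176983 of ESC and 174154 of EpiSC. Lists of equal length are thus almost bound to leave similar numbers without overlap, and their order decides nothing. Without chromosome 8, on which ESC sites were dense, 59.6% of ESC sites had no EpiSC overlap. Without chromosomes 7, 12 and 18, on which EpiSC sites were few, the share was 58.7%.

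Sites present in 1 of the pluripotent lists lay closer to sites of the other than in shifted lists, as did sites of every other pair. The median distance from an autosomal ESC site without overlap to the nearest EpiSC site was 1344 bp, against 3307 bp in shifted lists, and 41.1% lay within 1 kb of one, against 23.4%. From EpiSC sites to ESC the median was 1778 bp, against 4896 bp in shifted lists. From MEF sites to NSC it was 1466 bp, against 2402 bp. Beside shifts of 50 to 500 kb, an addition made after the data were seen, the medians in shifted lists were 1820 bp for ESC to EpiSC, 2744 bp for EpiSC to ESC and 2072 bp for MEF to NSC. In 100-kb windows the numbers of ESC and EpiSC sites rose and fell together, with a Spearman correlation of 0.84 across windows. NSC and MEF followed with 0.62. The other pairs were lower, at 0.45 for EpiSC and MEF, 0.44 for EpiSC and NSC, 0.35 for ESC and NSC and 0.34 for ESC and MEF. The highest correlation in any shifted list was 0.0966. Windows open in 1 pluripotent cell type alone were few and unevenly split: 70 autosomal windows held 5 or more ESC sites and no EpiSC site, and 453 held 5 or more EpiSC sites and no ESC site. The split was narrower with windows of 200 kb, where the numbers were 56 and 127, and with windows of 50 kb they were 108 and 839.

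The rule for named windows picked out regions in mm9 coordinates. The windows with the most ESC sites and no EpiSC site all lay on the X chromosome, where the EpiSC list had no site at all: 7500001 to 7600000 with 30 ESC sites, 7300001 to 7400000 with 27 and 11800001 to 11900000 with 27. Among autosomes, a choice made after the values were seen, these were chromosome 4 from 143900001 to 144000000 with 26 ESC sites, 1 NSC site and 7 MEF sites, chromosome 13 from 62300001 to 62400000 with 22 ESC sites, no NSC site and 1 MEF site, and chromosome 6 from 60900001 to 61000000 with 21 ESC, 36 NSC and 18 MEF sites. The windows with the most EpiSC sites and no ESC site were also open in somatic cells. They were chromosome 15 from 90100001 to 90200000 with 30 EpiSC, 86 NSC and 22 MEF sites, chromosome 19 from 49700001 to 49800000 with 23, 11 and 29, and chromosome 19 from 50300001 to 50400000 with 22, 46 and 30. The window with the most sites of its cell type was chromosome 8 from 34900001 to 35000000 in ESC, with 83 sites, chromosome 11 from 96100001 to 96200000 in EpiSC, with 75, and chromosome 9 from 41300001 to 41400000 in MEF, with 81. In NSC the first 3 windows lay in the dense domain of chromosome 14 described further on, with 95 sites each.

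Merging the 4 lists gave 1134236 regions, most of them seen in a single cell type. Regions of 1 list numbered 749293 (66.1%), those of 2 lists 246163 (21.7%), those of 3 lists 92789 (8.18%), and 45991 (4.05%, 95% interval 4.02 to 4.09) were open in all 4. NSC had the most regions of its own, 265500, followed by MEF with 188128, ESC with 176949 and EpiSC with 118716. With lists of equal length NSC and MEF were close, at 192187 and 190609, followed by ESC with 164718 and EpiSC with 143008. Among pairs, NSC with MEF (72107) and ESC with EpiSC (61376) stood above the remaining 4, which ranged from 19904 for ESC with MEF to 36901 for EpiSC with NSC. With lists of equal length the first of these numbers was 54296 and the second 73873, so that their order turned round.

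**Figure D1:**
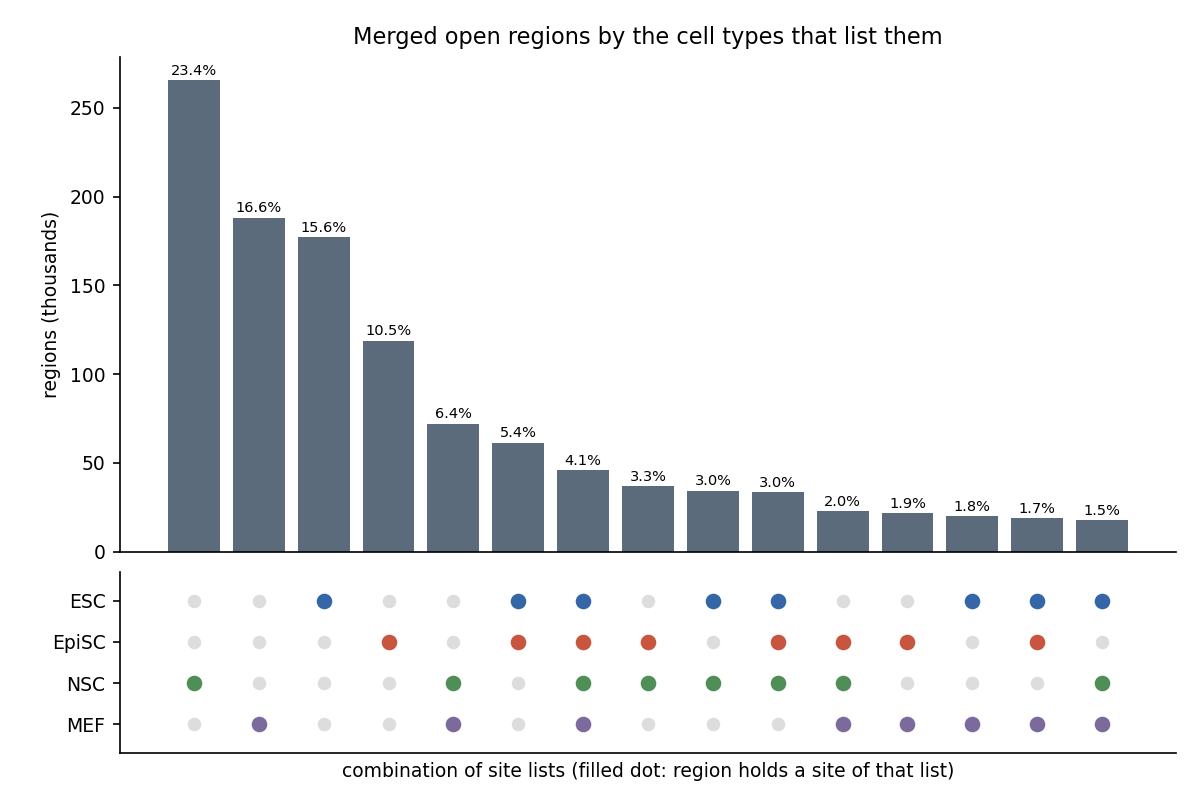
Numbers of merged regions (bars, in units of 1000) for each of the 15 combinations of site lists, with filled dots below each bar for the lists that hold a site in it and the share of all 1134236 regions above it. The 4 bars of a single list are the highest, and NSC with MEF (72107) and ESC with EpiSC (61376) come next.

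The score of sites rose step by step with sharing in the pluripotent cells and not in the somatic ones. The median score of ESC sites was 2.85 where no other list had a site, 3.48 with 1, 4.23 with 2 and 7.26 with all 3 other lists. In EpiSC it went from 2.61 to 4.47. In NSC it was 3.95 for sites of no other list and 5.39 for sites of all, with 3.65 in between for sites of 2 other lists, and in MEF 3.33 and 3.68, with 3.07 in between. Width rose too, from 328 to 622 bp in ESC, 275 to 630 bp in EpiSC, 285 to 730 bp in NSC and 281 to 524 bp in MEF. Among sites 250 to 350 bp wide, scores still rose from 2.19 to 4.16 in ESC and from 2.39 to 3.12 in EpiSC, and fell from 3.60 to 3.13 in NSC and from 3.03 to 2.5 in MEF. The score has no stated unit, so these steps hold within each list.

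Sites were spread unevenly over the chromosomes. ESC were dense on chromosome 8, with 1.47 times the autosomal median density and 1.53 times the relative density of the other lists. EpiSC were dense on chromosome 11 (1.76 times the autosomal median, 1.37 times the other lists) and sparse on chromosomes 18 (0.70 and 0.69 times), 12 (0.68 and 0.76 times) and 7 (0.76 and 0.86 times). Scores of EpiSC sites found in all 4 lists were 0.70, 0.71 and 0.73 times the autosomal median on chromosomes 18, 12 and 7 and 1.14 times on chromosome 11. The highest was 1.19 times, on chromosome 17. Density and score did not go together on every chromosome: on chromosome 5 the EpiSC density was 1.18 times that of the other lists with a relative score of 0.90, and on chromosome 9 these were 1.04 and 0.86. For ESC on chromosome 8 that score was 1.03 times the median. Across autosomes the SD of this relative score was 0.158 in EpiSC, 0.0403 in ESC, 0.0726 in NSC and 0.0473 in MEF. The X chromosome was sparse in every list. It held 0 EpiSC, 2992 ESC, 4219 NSC and 7244 MEF sites, at 0, 0.10, 0.11 and 0.25 times the autosomal median density. The Y chromosome held 61 ESC and 20 MEF sites and none in the other lists.

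**Figure D2:**
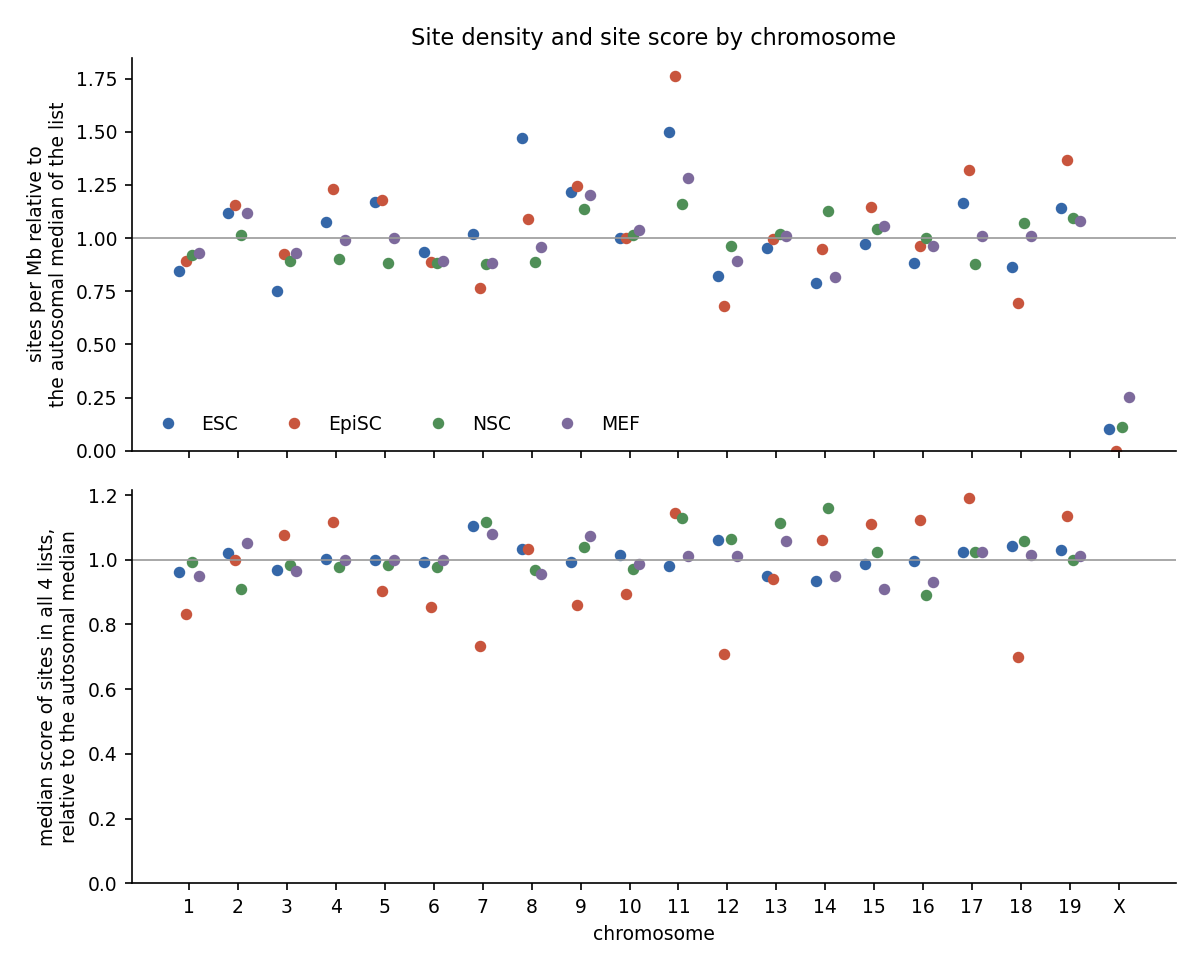
Top, sites per Mb of each chromosome relative to the autosomal median of the same list (points, 4 lists); bottom, median score of sites found in all 4 lists relative to the autosomal median, for autosomes. ESC stand apart on chromosome 8 in density (1.47), and EpiSC on chromosomes 7, 12 and 18 in both measures (scores of 0.73, 0.71 and 0.70).

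NSC had an extended domain of dense, though not continuous, sites on distal chromosome 14, from 86000001 to 121000000. It held 18366 NSC sites, or 525 per Mb against 219 per Mb on the other autosomes, a ratio of 2.40, and NSC sites covered 32.2% of its bases. The density was broken from 89000001 to 93000000, where the 4 bins of 1 Mb held 44 to 72 NSC sites each, and few in the other lists (11 to 27 in ESC, 17 to 26 in EpiSC and 68 to 87 in MEF). A total of 6 of the 35 bins of the domain lay below the density of other autosomes. Beyond the domain, the bins of 1 Mb that start at 122000001 and 123000001 held 22 and 26 NSC sites. In the same bins ESC had 464 and 87 sites, EpiSC 325 and 148, and MEF 125 and 213. In the other lists the domain was poorer than other autosomes, with ratios of 0.411 in ESC, 0.605 in EpiSC and 0.820 in MEF and at most 4.70% of bases covered. NSC scores there had a median of 6.80, against 3.88 on other autosomes, and 69.6% of the NSC sites lay in no other list, against 46.8%. Without the domain, 47.0% of NSC sites lay in no other list, against 47.8% with it.

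**Figure D3:**
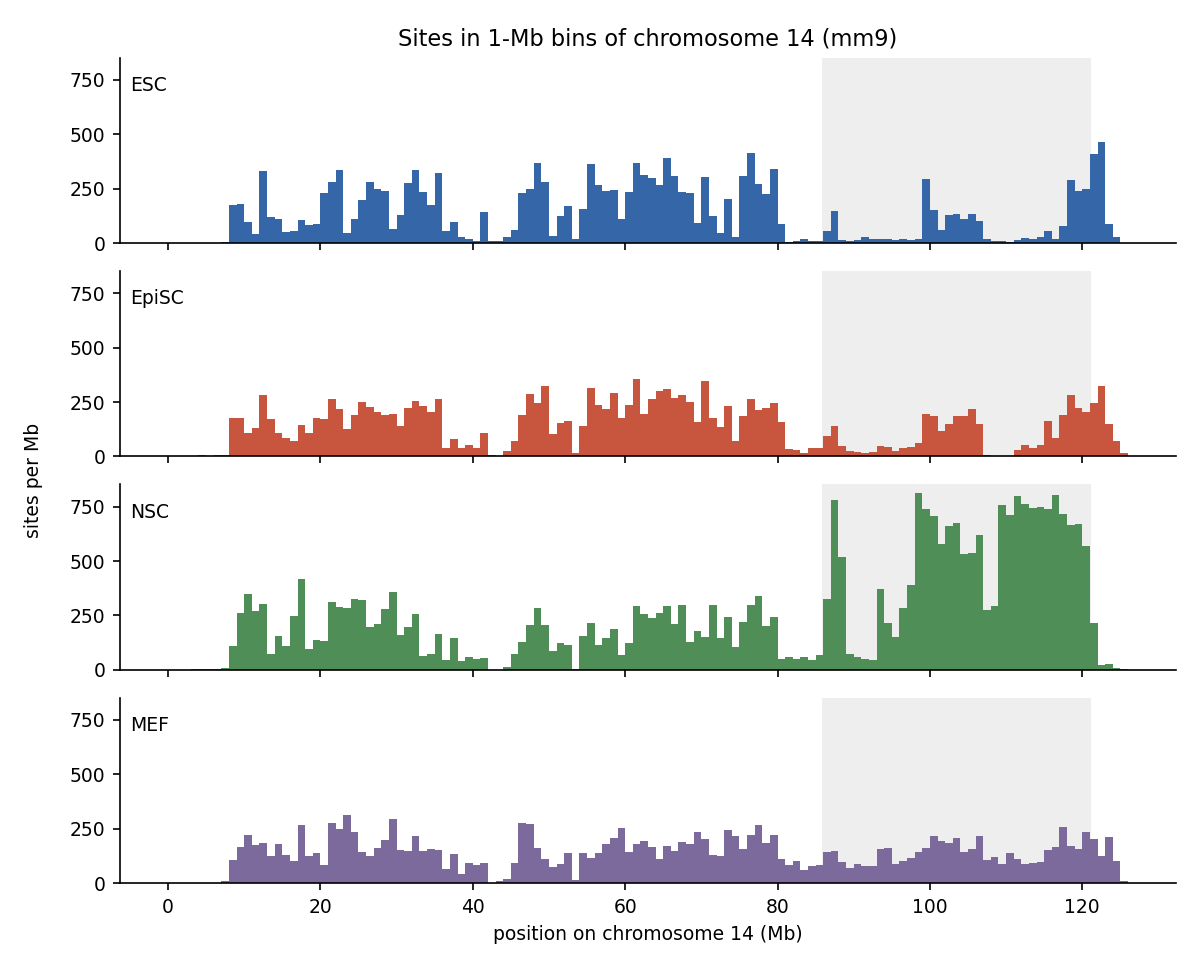
Sites in 1-Mb bins (bars, sites per Mb) along chromosome 14 in mm9 coordinates for the 4 lists, with the domain from 86 to 121 Mb shaded. NSC bars in the shaded part average 525 sites per Mb, against 141 in MEF, 95.4 in EpiSC and 73.5 in ESC. In the gap from 89 to 93 Mb the averages are 55.8 sites per Mb in NSC, 77.75 in MEF, 21.25 in EpiSC and 17.5 in ESC.

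The highest-scoring sites of each list were named by the rule set beforehand. In EpiSC the 3 highest of the whole list lay side by side on chromosome 8, at 125950195 to 125952657 (score 144), 125952828 to 125953845 (120) and 125955275 to 125956973 (99.1), and the neighbour at 125957089 to 125957498 (83.1) was the third highest of those in no other list. In ESC the highest scores were 39.0 at chromosome 15, 31348872 to 31349102, also open in EpiSC and NSC, 35.9 at chromosome 13, 92047840 to 92048133, open in all lists, and 34.6 at chromosome 13, 66781861 to 66781939, in no other list. Next among sites of ESC alone came chromosome 13, 65516061 to 65516201 (32.8) and chromosome 10, 70303975 to 70304367 (31.2). In NSC the highest were chromosome 13, 83874795 to 83875109 (40.5, also in MEF), chromosome 15, 92265091 to 92265218 (38.7, also in EpiSC) and chromosome 4, 59109302 to 59109806 (38.3, in all lists). Those in no other list were chromosome 15, 40538104 to 40538362 (37.0), chromosome 14, 98270947 to 98271487 (34.8), inside the dense domain, and chromosome 5, 4503371 to 4503675 (34.6). In MEF they were chromosome 4, 149131438 to 149131499 (35.0, in no other list), chromosome 7, 66931918 to 66931974 (34.8, also in EpiSC) and chromosome 7, 54861673 to 54861883 (30.7), and beyond these, among sites of MEF alone, chromosome 7, 54839015 to 54841205 (27.3). Several of these sites are under 100 bp wide, and single narrow sites of high score have no replicate check.

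High-scoring sites also formed compact runs. There were 2 runs in ESC, 6 in EpiSC, 43 in NSC, of which 32 lay on chromosome 14, and 13 in MEF. The EpiSC run on chromosome 8, from 125950195 to 125957785, had 8 sites with a median score of 68.8, or 23.7 times the list median, and covered 83.8% of its 7591 bp. ESC and NSC had no site in it, and MEF had 2 with scores up to 10.4. An EpiSC run on chromosome 17, from 35634698 to 35655066, had 7 sites covering 94.1% of its 20369 bp with a median score of 29.4, or 10.1 times the list median. This stretch was also open in ESC, which covered 77.5% of it with scores up to 13.6. The strongest MEF run, on chromosome 7 from 54837651 to 54866332, had 22 sites with a median score of 18.5, or 5.59 times the list median, and covered 70.5% of its 28682 bp. EpiSC and NSC had 1 small site each in it and ESC none. The edges of these runs were abrupt, with no MEF site within 5 kb of the run on chromosome 7 and flanking EpiSC scores of at most 8.69 on chromosome 8 and 9.37 on chromosome 17.

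**Figure D4:**
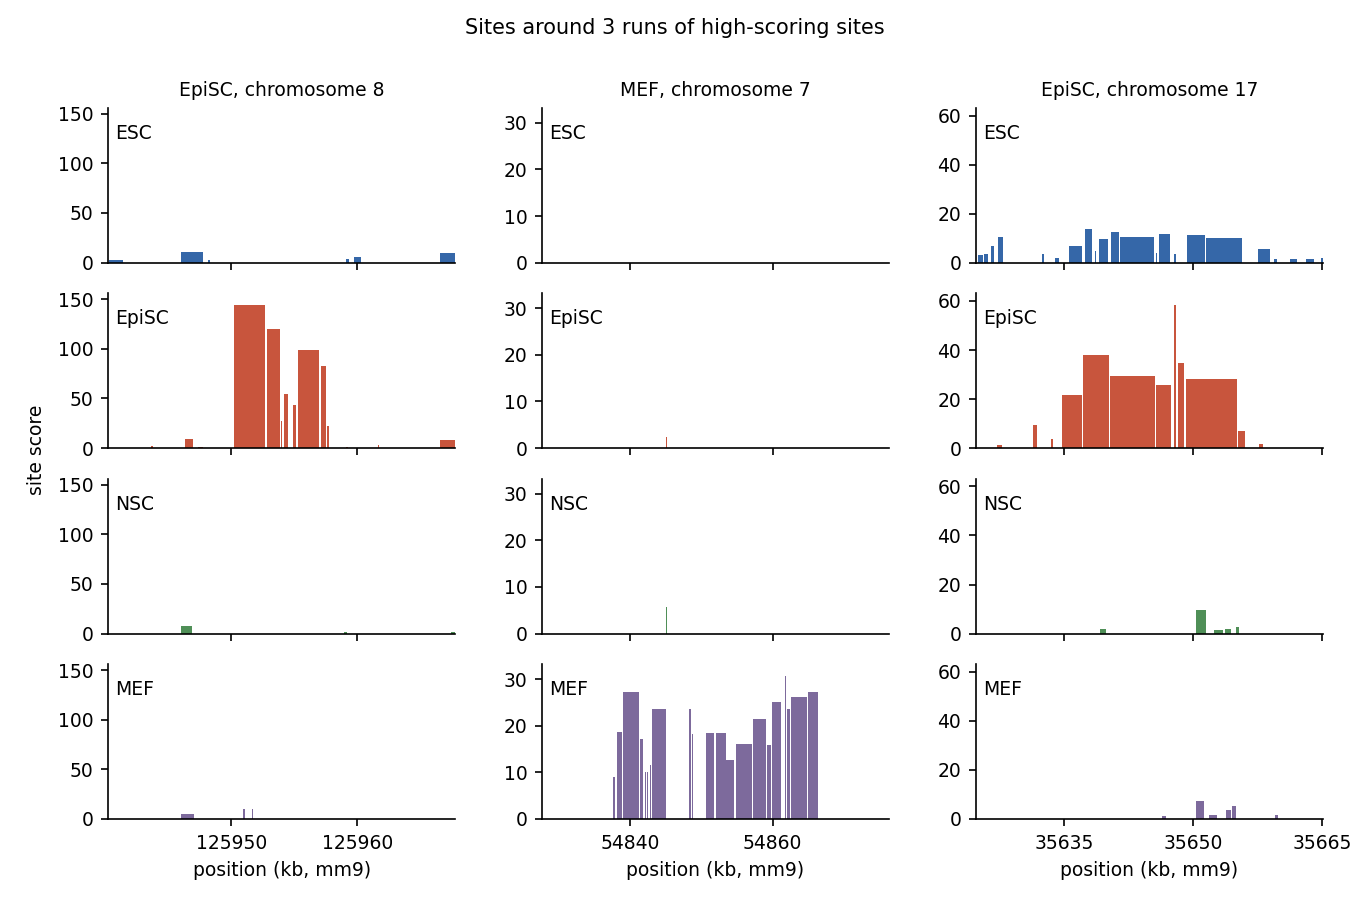
Site scores (bar height; bar width is site width) around 3 runs of high-scoring sites, with positions in kb of mm9, for the 4 lists. EpiSC scores reach 144 on chromosome 8 and 58.4 on chromosome 17, and MEF scores reach 30.7 on chromosome 7; scores of different lists are not on a scale known to be shared.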

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

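Leaving out distal chromosome 14, chromosomes 7, 12 and 18, or chromosome 8, and distances beside shifts of 50 to 500 kb, were chosen after the data were seen; the other alternatives were planned. Of the main values under these alternatives, 72 stayed within their interval, or within 1.5 times for counts, and 75 moved; of the single shares of sites with no overlap and the distances to the nearest site, 3 stayed and 31 moved. The intervals of shares cover the counting of sites alone and are narrow. No paired analysis was possible because each cell type had 1 list, and leaving out a replicate was not possible for the same reason. The planned annotation of sites with genes and the tests of gene lists were not run. Depth is unknown and limits how far numbers of sites can be compared. Except where fewer sites or a different chance placement make the change by construction, the cause was not tested.

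Overlap shares are given here in the order EpiSC sites in ESC, ESC in NSC, MEF in ESC, EpiSC in NSC, EpiSC in MEF and MEF in NSC. Requiring 50% of the shorter site gave 41.6%, 29.3%, 21.4%, 34.4%, 24.7% and 34.5%. The 50% of each list with the highest scores gave 36.9%, 22.4%, 16.8%, 28.6%, 21.2% and 31.3%. Lists of equal length gave 42.4%, 24.1%, 22.0%, 28.1%, 25.6% and 32.4%. EpiSC sites in ESC remained the highest share in these 3 settings. On autosomes MEF sites in ESC came to 25.3% and MEF in NSC to 40.6%. Without distal chromosome 14 the shares in NSC were 32.9% of ESC, 38.5% of EpiSC and 39.7% of MEF sites. With shifts of 50 to 500 kb the ratios to chance, in the same order, were 1.86, 1.45, 1.48, 1.75, 1.83 and 1.94, so that MEF with NSC and not EpiSC with ESC was highest.

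Keeping the 50% of each list with the highest scores left 220927 ESC, 193656 EpiSC, 277934 NSC and 215955 MEF sites, with median widths of 472, 354, 359 and 342 bp. It left 147328 ESC sites without EpiSC overlap and 122217 EpiSC sites without ESC overlap. There were then 649751 regions, with 116894 of ESC alone, 167312 of NSC alone, 121003 of MEF alone, 32881 of ESC with EpiSC, 34553 of NSC with MEF and 15275 of all 4 lists. Merging sites under 200 bp apart gave median widths of 391 bp in ESC, 347 in EpiSC, 348 in NSC and 332 in MEF.

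Window correlations with lists of equal length were 0.24 for ESC and NSC, 0.26 for ESC and MEF, 0.33 for EpiSC and NSC, 0.36 for EpiSC and MEF and 0.60 for NSC and MEF. With windows of 50 kb they were 0.80 for ESC and EpiSC and, in the order just given, 0.33, 0.30, 0.42, 0.41 and 0.58. With windows of 200 kb they were 0.87 for ESC and EpiSC, 0.37 for ESC and MEF, 0.45 for EpiSC and NSC, 0.48 for EpiSC and MEF and 0.65 for NSC and MEF. Without distal chromosome 14 they were 0.37 for ESC and NSC, 0.45 for EpiSC and NSC and 0.64 for NSC and MEF, and without chromosomes 7, 12 and 18 ESC and EpiSC stood at 0.85. ESC and EpiSC remained the highest pair throughout. Windows of 5 or more ESC sites and no EpiSC site numbered 108 at 50 kb, and those of EpiSC without ESC 839 at 50 kb and 127 at 200 kb. With lists of equal length the ESC density on chromosome 8 was 1.48 times that of the other lists and the NSC density on chromosome 14 was 1.56 times.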

Other observations

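The tests in this part were all chosen after the values they bear on had been seen. Sites of 2 kb or more were rare, and most of them overlapped a site of another list. ESC had 7793 of them, NSC 7444, EpiSC 4593 and MEF 1176. Of the wide EpiSC sites 98.9% overlapped an ESC site and 19 lay in no other list, whereas 81.9% of the wide ESC sites overlapped an EpiSC site and 825 (10.6%) lay in no other list. Of these 825, 167 were on chromosome 8. Wide sites of NSC overlapped all 3 other lists in 61.7% of cases, those of MEF in 74.1%, those of EpiSC in 65.0% and those of ESC in 41.1%. A wider site meets a site of another list more often by chance. The shares of wide sites were not set beside shifted lists or sites matched on width. Whether wide sites are shared beyond what their width gives was therefore not tested.

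Of the 6 EpiSC runs, 3 held sites of MEF and none of ESC or NSC, and the other 3 held sites of both ESC and NSC. On chromosome 10, from 7231208 to 7236388, EpiSC had 6 narrow sites covering 14.1% of the stretch with a median score of 28.6, MEF had 5 sites with scores up to 19.7, and ESC and NSC had none. On chromosome 4, from 133354389 to 133358778, EpiSC had 5 sites with scores up to 34.7 and MEF 1 site with a score of 9.15, covering 3.53% of the stretch. The strongest NSC run lay on chromosome 11, from 6368841 to 6376602, with 5 sites and a median score of 22.9. On chromosome 8, where ESC sites were 1.53 times as dense as in the other lists, the ESC score at sites of all lists was 1.03 times its autosomal median.

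The dense NSC domain on distal chromosome 14 was weighed against several explanations. An excess of reads there in every library is argued against by the other lists, of which the densest, MEF, reached 0.820 times its density on other autosomes. With lists of equal length the NSC density ratio was 3.06, but this does not decide on the length of the NSC list. Those lists keep the highest-scoring sites, and NSC sites in the domain scored higher than elsewhere (median 6.80 against 3.88), so the ratio was bound to stay high. Extra copies of all or part of the segment in the NSC culture may account for it: NSC scores at sites of all 4 lists were 2.13 times those on the rest of the chromosome, against 0.710 in ESC, 0.864 in EpiSC and 0.955 in MEF. Open chromatin particular to the NSC, whose sites covered 32.2% of the domain, cannot be told apart from extra copies, because DNA of the same cells without enrichment was not analysed here. The low number of NSC sites beyond the domain was not tested against either explanation. Whether the sparse stretch from 89000001 to 93000000, with 0.255 times the density of other autosomes in NSC and 0.0978, 0.135 and 0.451 times in ESC, EpiSC and MEF, shares in the excess was not tested.

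The compact runs of EpiSC on chromosome 8 and of MEF on chromosome 7 were weighed against several explanations. An excess of reads there in every library is argued against by ESC and NSC, which together had 0 sites at or above their own 95th percentile in the 2 runs, although MEF had 2 such sites in the EpiSC run. Extra copies or added DNA of the blocks and open chromatin over them cannot be told apart, because DNA of the same cells without enrichment was not analysed here. Neither the coverage of 73.3% of the bases with no site in any other list nor the median score of 23.7 times the list median in EpiSC decides, since runs were picked for dense sites of high score. In the EpiSC run on chromosome 17, ESC had 4 sites at or above its own 95th percentile and NSC and MEF had none. For that run, too, extra copies or added DNA and open chromatin cannot be told apart, for the same reason as above.

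EpiSC sites differed in level from chromosome to chromosome. Over the 19 autosomes EpiSC density relative to the other lists and EpiSC score at sites of all lists rose together. Pearson r was 0.846 (two-sided permutation p = 1e-05, the smallest that the permutations can give, adjusted p = 4e-05 over 4 lists) and Spearman rho was 0.83 (permutation p = 1e-05). By the same permutation test r was 0.38 in ESC (p = 0.11), 0.36 in NSC (p = 0.134) and 0.067 in MEF (p = 0.786), and chromosomes are not replicates. Leaving out the chromosomes whose density over the other lists lay farthest from the median gave r = 0.81 in EpiSC (without 11 and 18). It gave 0.33 in ESC (without 3 and 8), 0.022 in NSC (without 14 and 18) and 0.036 in MEF (without 5 and 18). A few regions of low level are argued against as the source by bins of 10 Mb with at least 20 EpiSC sites found in all lists. On chromosomes 7, 12 and 18, 100% of the 36 such bins (of 39 with any such site) lay under the EpiSC median score of 4.47 at those sites. Elsewhere 84 of 216 (of 219) did. These chromosomes had been picked for low EpiSC levels, so a higher share than elsewhere follows from that choice. The choice did not require every bin to lie low, and the highest of the 36 stood at 3.78. Unequal chromosome numbers in the EpiSC culture may account for the pattern, but r = 0.846 is not specific to them, since any cause that moves density and score together gives a positive r, and the size they would give was not simulated. Base composition of the chromosomes cannot be told apart with certainty, because the genome sequence was not used here. With ESC site density as a stand-in, EpiSC scores in the bins of chromosomes 7, 12 and 18 were 0.722 times those of matched bins, and below them in 36 of 36. These chromosomes had been picked for low EpiSC levels and the matched bins came from other autosomes. The ratio thus largely restates that choice and does not decide.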
